A study of Homo sapiens with 15 samples.

How the data were processed

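RNA was measured in 15 libraries of the H9 line, 3 in each of 5 groups that the labels describe as independent biological replicates. Per the labels' protocols, cDNA was primed with oligo-dT and sequenced as single-end reads. The deposited table holds raw read counts per gene, 1 column per library and lane, for 34817 genes with versioned Ensembl identifiers. Per the submitters' processing notes, TopHat2 2.1.1, featureCounts and Subread 1.5.2 were used with the hg19 build, with no role given. The strand setting, the treatment of reads with several matches and any row filter are not given in the sources used here. Reads of near-identical genes and of antisense partners can therefore not be told apart. Gene symbols were matched by Ensembl identifier for 32857 genes (94.4%). Of these, 166 had a symbol already held by a gene with more counts and kept their identifier as name. No coordinates are printed because no hg19 annotation was used here. CD24 and CD99, 2 of the 66 surface antigens, were not analysed here, and MYLPF, on the sarcomere list, was tested under its current symbol MYL11 and stayed outside that list.

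The counts of the 2 lanes of each library were summed. Lanes of 1 library differed by little more than sampling noise (chi-square per degree of freedom 1.23 to 1.37), and replicate libraries by more (2.10 to 90.2). Totals were 17373554 to 18482239 counts per library. A count of 3, used as the floor, corresponds to about 0.17 CPM, and bounds were set from 3 counts over the 3 libraries of a group. Intervals are exact 95% binomial intervals of counts and cover counting error only.

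All 15 libraries were fitted in 1 model with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default low-count filter with a minimum count of 10 and a term for the group. The filter left 17721 genes and removed 17096. Contrasts were tested with the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.0372. Principal components used the 500 most variable genes as log2 CPM with a prior count of 2. The 4 comparisons were D4 with ESC, D10P with D4, D10P with D10N, and Diff with D10P. They share libraries, so their calls are not independent.

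The design, the lists, the rule for named genes and the alternative settings were fixed before the data were examined. The 31 lists with 568 genes covered pluripotency, primitive streak and presomitic mesoderm, somite and dermomyotome, myogenic regulators, satellite cell and myoblast surface proteins, surface antigens, sarcomere, excitation-contraction coupling, neuromuscular junction, muscle energy metabolism, proliferation and cell cycle exit. They further covered the Notch pathway, target genes of Wnt, BMP, TGF-beta and activin, glucocorticoid, and FGF and ERK signalling, dissociation and immediate early stress, imprinted growth genes and anterior and posterior HOX genes. Markers of other cell types were neural, neural crest and Schwann, endothelial and blood, cardiac, sclerotome with cartilage and tendon, fibroblast and mesenchyme, smooth muscle, epithelial and endoderm genes. Some genes stand on several lists. Camera (limma 3.58.1) with a preset correlation of 0.01 tested the 30 lists with 5 or more tested members, adjusted over the lists of a comparison. It called 11, 17, 17 and 10 lists in the 4 comparisons, of which 5, 5, 7 and 2 were also called with an estimated correlation. That correlation was estimated from the fit of all 15 libraries, so it also holds the spread of libraries outside a comparison. For the sarcomere list it was 0.543, 0.575, 0.473 and 0.535 in the 4 comparisons. In 16 of 120 list tests the median, mean and test differed in sign, none of them called.

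Genes named in the text are PAX7, MYF5, MYOD1, MYOG, PAX3, POU5F1, NANOG, TBX6, MYH3 and MME. Per comparison they are also the 10 highest and 10 lowest fold changes among called genes with a symbol, a mean of at least 10 CPM in the higher group and no overlap between the groups. Chance alone gives no overlap between 3 libraries and 3 in 10% of splits. Per list they are the 2 highest and 2 lowest called members, in that order as far as needed. Some genes that meet this rule are not reported here. ENSG00000254339, whose symbol is its identifier, was among the lowest of D4 against ESC. SOX10 in the plot of 9 genes, SIX4, LRP4, AGRN, ERBB3 and MITF follow the list part of the rule where they were called. TBXT, MSGN1, MESP2, RIPPLY2 and the genes of the weighed patterns were chosen after their values were seen.

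The alternatives were RLE factors, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, only the 6 libraries compared, a minimum log2 change of 1, an adjusted p of 0.01, leaving out each library, and for lists an estimated correlation and fry. The replicate block and the fit without both day-10 libraries numbered 3 were chosen after seeing the data. The labels give the day-10 groups no shared replicate numbers, and the numbers were taken from the table's column names. Deviations from the group means correlated between same-numbered D10N and D10P libraries at r = 0.491, 0.676 and 0.753 across genes, and between others at -0.650 to 0.189, so the numbers were taken to pair the samples. Deviations cancel within a group, so the lower values between others are in part forced and are no independent contrast. Genes are not independent replicates in these coefficients.

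The procedure was tested on simulated data for D10P against D10N with 17460 genes. It recovered 46% of 100 genes changed 2-fold and 72% of 100 changed 4-fold, with 11 false calls, and 1 of 200 unchanged lists had an unadjusted p under 0.05. Genes were drawn independently, with the same dispersion of a gene in all groups and no pairing of the day-10 libraries. The simulation therefore does not show how many false calls correlated genes and unequal spreads give in the real libraries. Other myoblast data named in the series description were not used here.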

Results

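Gene expression was measured by sequencing of poly(A)-primed RNA in H9 cells, an established human embryonic stem cell line, on the way to skeletal muscle. The cells carry fluorescent reporters at MYF5 and PAX7. MYF5 encodes a transcription factor that opens the muscle programme, and PAX7 marks muscle progenitors and satellite cells. The 15 libraries form 5 groups of 3 biological replicates. They are undifferentiated cells at day 0 (ESC), the culture after 4 days in the first medium (D4), the day-10 cells sorted without (D10N) or with (D10P) MYF5-EGFP, and cells differentiated further from the positive fraction (Diff). The Diff libraries were taken as the day-20 myotubes because the design leaves them no other group. Each library held 17373554 to 18482239 counted reads, so 3 counts correspond to about 0.17 CPM, counts scaled to library size. Levels below are mean CPM ± SD with n = 3 libraries. Fold changes are log2 with their standard error, ratios given as a range are 95% counting intervals, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 17721 genes. Where the text states that none of a list's genes rose, or that none fell, this is by edgeR, and none did at an unadjusted p under 0.05, with DESeq2 or with limma-voom either, unless other counts are given. A direction that is not mentioned carries no such statement.

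On the first 2 principal components the ESC and D4 libraries lay apart from the others. The day-10 fractions were less clearly parted, and D10N replicate 2 lay nearer to D10P replicate 3 than to D10N replicate 3. The first principal component of the 500 most variable genes held 72.04% of the variance and the second 19.4%. Correlations of log2 CPM across genes within a group were 0.992 to 0.994 for D4 and 0.994 for ESC. They were lower in the sorted fractions, at 0.960 to 0.982 in D10N and 0.965 to 0.990 in D10P, against 0.941 to 0.977 between the fractions. Genes are not independent replicates, so these coefficients describe the libraries only. The share of counts from mitochondrial genes was 3.89% ± 0.146 in ESC, 3.91% ± 0.0537 in D4, 3.50% ± 0.350 in D10N, 4.12% ± 0.406 in D10P and 3.29% ± 0.0183 in Diff. Of the genes tested, 13970 differed among the 5 groups.

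**Figure D1:**
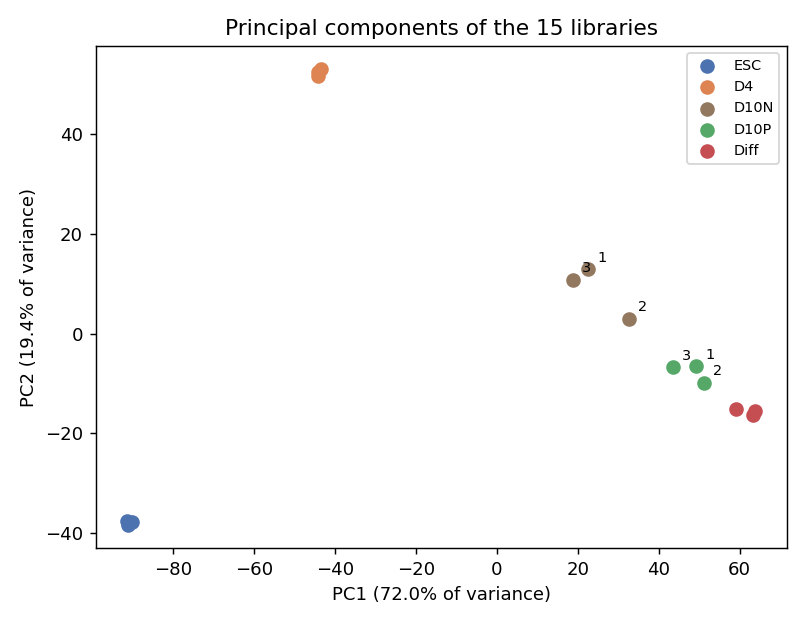
Principal components 1 and 2 of log2 CPM of the 500 most variable genes, with 1 point per library, the 5 groups in colour and the day-10 libraries marked with their replicate number. The first axis holds 72.04% and the second 19.4% of the variance, and the day-10 fractions spread more within their group than ESC or D4.

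The reporter genes were followed first. MYF5 (ENSG00000111049.3) was at 0.132 ± 0.0881 CPM in ESC and 0.0185 ± 0.0320 in D4, which is 1 count over the 3 D4 libraries. That difference was not called (adjusted p = 0.0507) but was with RLE factors (0.0483), with at least 1 CPM in 3 libraries (0.0461) and without ESC replicate 1 (0.0307) or D4 replicate 1 (0.0231). MYF5 reached 2.15 ± 0.757 in D10N, 33.6 ± 6.12 in D10P and 18.7 ± 1.87 in Diff. The positive fraction held more MYF5 than the negative one in all 3 replicates (log2 fold change 3.97 ± 0.29, adjusted p = 7.49e-06). PAX7 (ENSG00000009709.7) followed another course. It was at 0.246 ± 0.282 CPM in ESC and 39.5 ± 8.42 in D4, then at 0.524 ± 0.522 in D10N, 1.40 ± 1.22 in D10P and 2.58 ± 0.807 in Diff. The related gene PAX3, a regulator of early muscle and neural crest progenitors, rose by day 4 from 0.132 ± 0.0667 to 182 ± 5.64 CPM. It was then at 218 ± 51.8 CPM in D10N, 177 ± 24.4 in D10P and 170.6 ± 11.96 in Diff.

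**Figure D2:**
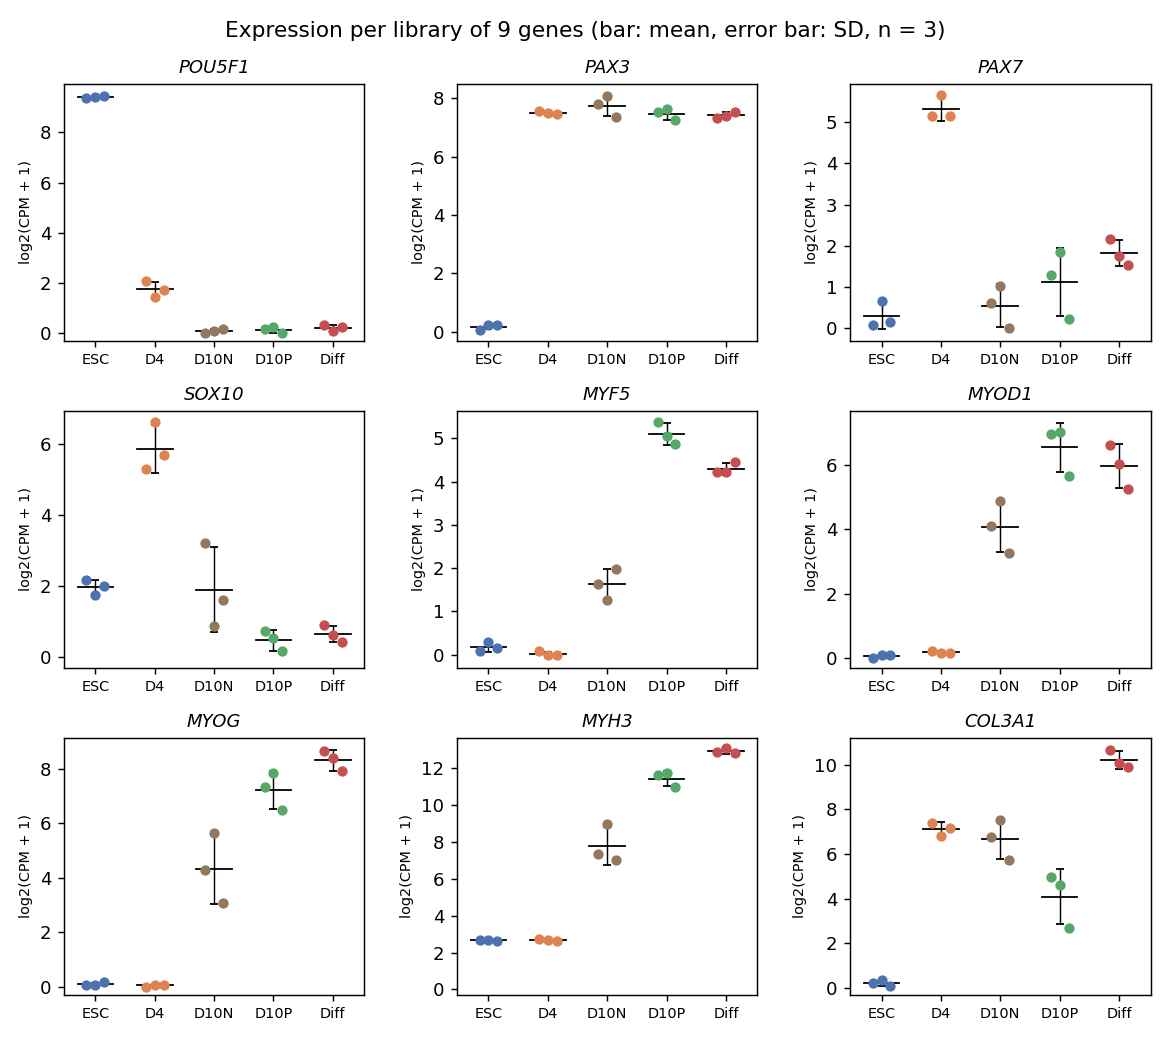
Expression of 9 genes in each library as log2(CPM + 1), with the 5 groups on the horizontal axis, 1 point per library, a bar at the mean and an error bar of 1 SD (n = 3). PAX7 and SOX10 are highest in D4 among the 5 groups, with means of 39.5 and 62.0 CPM, while MYF5, MYOD1 and MYOG are highest in the D10P or Diff libraries.

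The comparison of D4 with ESC shows how the culture differed after 4 days in the first medium, with time and medium changed together. This medium holds CHIR99021, which inhibits GSK3 and so activates Wnt signalling, and SB431542, which inhibits TGF-beta type receptors. By day 4 the pluripotency genes had fallen. POU5F1, a core pluripotency factor, went from 685 ± 24.6 to 2.41 ± 0.712 CPM (log2 fold change -8.15 ± 0.26, adjusted p = 1.04e-10). NANOG went from 71.7 ± 3.48 CPM to 3 counts over the D4 libraries, a ratio of 444 to 6295 (95% counting interval). Wnt target genes, HOX genes and PAX3 rose, and epithelial genes fell. Neural crest genes rose too, but their list's call was lost with an estimated correlation. In all, 9440 genes changed, 4710 higher and 4730 lower in D4.

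Of 21 tested pluripotency genes 18 fell and 1 rose. TDGF1 fell most (log2 fold change -12.00 ± 0.35) and may share reads with its copy TDGF1P3, which fell at least 590.2-fold to no reads in D4. The member that rose was FOXD3 (3.34 ± 0.41), which is also a neural crest gene. Of 16 Wnt target genes 13 rose, led by SP5 (9.01 ± 0.46) and LEF1 (8.47 ± 0.53), and BAMBI fell (-1.35 ± 0.40). All 13 tested HOX genes of paralog groups 1 to 5 rose. HOXD3 and HOXA3, without a read in ESC, rose at least 455-fold and 446-fold, bounds set from 3 counts over the group. Of 16 epithelial genes 13 fell and none rose, among them GRHL2, a regulator of epithelial identity (a ratio of 421 to 92798), and the adhesion gene CDH1 (-10.74 ± 0.56). Of 19 fibroblast and mesenchyme genes 12 rose, led by COL3A1 (9.64 ± 0.87), and THY1 fell (-3.52 ± 0.61). These 5 lists were called by camera with the preset correlation and with an estimated one, the latter at adjusted p = 0.00189, 0.00193, 0.00189, 0.00333 and 0.00333.

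Another 6 lists were called with the preset correlation only. Of 14 genes of the primitive streak and presomitic mesoderm 10 rose, led by CDX2 (a ratio of 269 to 3824), and 2 fell, DLL3 (-3.81 ± 0.48) and TBX6 (-2.56 ± 0.54), which marks presomitic mesoderm. TBXT and MSGN1 did not pass the count filter, with at most 8 and 2 counts in any library, and were not called without it (adjusted p = 0.457 and 0.254), while MESP2 and RIPPLY2, also below the filter, were then lower (0.00207 and 0.0124). That list had adjusted p = 0.151 with an estimated correlation and 0.0699 without the count filter. Of 18 somite and dermomyotome genes 7 rose, led by PAX3 (10.37 ± 0.29) and MEOX1 (a ratio of 239 to 3392), and TCF15 (-1.86 ± 0.45) and SIX4 fell (adjusted p = 0.422 with an estimated correlation). Of 13 neural crest and Schwann genes 10 rose and none fell, with TFAP2B at least 1616-fold and TFAP2A at least 363-fold higher (adjusted p = 0.151 with an estimated correlation). BMP target genes rose in 9 of 14 cases, led by NOG (7.96 ± 0.78) and MSX1 (7.95 ± 0.90), and fell in 2 (adjusted p = 0.546 with an estimated correlation). Imprinted growth genes rose in 9 of 12 cases, led by PLAGL1 (5.30 ± 0.32) and IGF2 (5.29 ± 0.37), and none fell (adjusted p = 0.0846 with an estimated correlation). The sclerotome, cartilage and tendon list, with 5 of 11 genes higher and 4 lower, had adjusted p = 0.0946 with an estimated correlation, 0.246 without the count filter, 0.0610 without ESC replicate 1 and 0.0723 without ESC replicate 2. Adjusted over the list alone, the counts of these 11 lists were as given except for 13 fibroblast genes that rose.

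The remaining 19 lists were not called in D4 against ESC. Among them, 8 of 12 cell cycle exit genes rose and 1 fell, 1 of 8 cardiac genes rose and 6 fell, and 4 of 15 myogenic regulators rose and 1 fell. With only the 6 libraries compared these lists were called (adjusted p = 0.0127, 0.0236 and 0.00127), cell cycle exit also without the count filter (0.0138) and the regulators without D4 replicate 3 (0.0487). Fry called 8 of the 19 lists. Of 14 TGF-beta and activin target genes 2 rose and 7 fell, 9 adjusted over the list alone. Those that fell most were NODAL, which had no read in D4 and was at least 16.9-fold lower, and LEFTY2 (a ratio of 27.8 to 6245), which may share reads with LEFTY1. MYH3, an embryonic myosin, was at 5.34 ± 0.228 CPM in ESC and 5.36 ± 0.193 in D4 (adjusted p = 0.998), and the membrane peptidase gene MME was at 35.2 ± 1.82 and 31.0 ± 6.94 (adjusted p = 0.562). The genes with the largest rise at 10 CPM or more were TFAP2B, ITGA8, HOXD3, HOXA3, HAGLR, BMP5, HOXD1, TFAP2A, HOXB-AS3 and HOXB9. HAGLR and HOXB-AS3 lie antisense to HOX genes, and the strand setting of the counting is not given in the sources used here, so their reads cannot be told from those of their partners. Tested against a minimum log2 change of 1, 3253 genes passed, 1214 higher and 2039 lower.

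The comparison of D10P with D4 shows how the sorted MYF5-EGFP-positive fraction differed from the day-4 culture. Muscle genes were higher. MYOG, a regulator of muscle differentiation, went from 2 counts over the D4 libraries to 159 ± 69.9 CPM, a ratio of 1164 to 34732 (95% counting interval). MYOD1 rose by 9.54 ± 0.75 on the log2 scale (adjusted p = 3.91e-07) and MYH3 by 9.06 ± 0.54 (adjusted p = 3.63e-08), to 2860.1 ± 750.0 CPM. PAX7 fell (log2 fold change -4.80 ± 0.73, adjusted p = 1.34e-04), as did POU5F1 (-4.59 ± 0.46), which was already low in D4. Wnt target and neural genes fell with them, and 7806 genes changed, 4195 higher and 3611 lower in D10P.

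Of 15 myogenic regulators 13 rose and PAX7 fell. The list's call held with an estimated correlation (adjusted p = 0.0466). Of 18 satellite cell and myoblast surface proteins 11 rose, led by the muscle cadherin CDH15 (7.65 ± 0.71) and the HGF receptor MET (6.14 ± 0.39), and SDC3 fell (-0.65 ± 0.12; adjusted p = 0.0195 with an estimated correlation). Of 17 genes of excitation-contraction coupling 14 rose, led by CASQ2, a calcium store protein, at a ratio of 749.5 to 22374, and 1 fell (adjusted p = 0.0494 with an estimated correlation). Of 16 Wnt target genes 12 fell and none rose, with SP5 at -8.17 ± 0.43 and NOTUM at -6.36 ± 0.44 (adjusted p = 0.00124 with an estimated correlation). Of 21 neural genes 14 fell, led by NEUROG2, at least 71.6-fold lower, and 4 rose, led by POU4F1 (8.52 ± 0.69) and DCX (5.28 ± 0.32; adjusted p = 0.0466 with an estimated correlation).

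For 12 further lists the call was lost with an estimated correlation. Of 43 sarcomere genes 37 rose, led by MYOZ2, at least 450.3-fold, and LMOD3, and LMOD2 fell (-2.48 ± 0.58; adjusted p = 0.0969 with an estimated correlation). Of 11 neuromuscular junction genes 9 rose, led by the acetylcholine receptor subunit CHRNA1 (a ratio of 2296 to 68514) and its organiser MUSK, at least 533-fold, while LRP4 and AGRN fell (adjusted p = 0.131 with an estimated correlation). Genes of muscle energy metabolism rose in 9 of 16 cases, led by CKM (7.59 ± 0.83), and fell in 1 (adjusted p = 0.443 with an estimated correlation). Somite and dermomyotome genes rose in 9 of 18 cases, among them TBX18 (a ratio of 190.5 to 2707), and PAX7 fell (adjusted p = 0.289 with an estimated correlation). Neural crest and Schwann genes fell in 8 of 13 cases, among them FOXD3 (-9.11 ± 0.63), and ERBB3 and MITF rose (adjusted p = 0.131 with an estimated correlation). BMP target genes fell in 10 of 14 cases, led by MSX2 (-5.61 ± 0.56), and 2 rose (adjusted p = 0.177 with an estimated correlation); the second medium holds the BMP receptor inhibitor LDN193189. HOX genes of groups 1 to 5 fell in 8 of 13 cases, led by HOXB1 (-9.18 ± 0.29), and 3 rose, led by HOXB5 (1.66 ± 0.24; adjusted p = 0.131 with an estimated correlation). Imprinted growth genes rose in 8 of 12 cases, with H19 reaching 4858 ± 1112 CPM and IGF2 2191 ± 581, and GRB10 fell (adjusted p = 0.0969 with an estimated correlation).

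Pluripotency genes fell in 12 of 21 cases and 1 rose (adjusted p = 0.0613 with an estimated correlation). Sclerotome, cartilage and tendon genes fell in 5 of 11 cases and 1 rose (adjusted p = 0.127 with an estimated correlation). Primitive streak and presomitic genes fell in 7 of 14 cases, led by WNT3A, at least 24.8-fold lower, and 2 rose. That list had adjusted p = 0.131 with an estimated correlation, 0.0718 without D10P replicate 3 and 0.143 without both day-10 libraries numbered 3. Of 64 surface antigens usable for sorting 28 rose, led by NT5E (9.57 ± 1.12), and 15 fell, led by FZD10 (-3.38 ± 0.70). That list had adjusted p = 0.466 with an estimated correlation and 0.124 without D10P replicate 3. MME rose from 31.0 ± 6.94 to 365 ± 123 CPM (adjusted p = 2.40e-07). PAX3 (adjusted p = 0.882) and TBX6 (adjusted p = 0.588) did not differ past the threshold. Adjusted over the list alone, 38 sarcomere and 10 energy metabolism genes rose, and 2 surface proteins, 13 Wnt target genes and 17 surface antigens fell.

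Among the 13 lists not called in D10P against D4, endothelial and blood genes rose in 6 of 11 cases and 2 fell, 7 and 3 adjusted over the list alone (adjusted p = 0.0528). That list was called without the count filter (0.0456), with only the 6 libraries compared (0.0336) and without D10P replicate 1 (0.0184) or 2 (0.0250). Cell cycle exit genes rose in 6 of 12 cases (adjusted p = 0.116), called without the count filter (0.0204) and with only the 6 libraries compared (0.0480). Epithelial genes fell in 5 of 16 cases and 1 rose (adjusted p = 0.140), called with only the 6 libraries compared (0.01004). FGF and ERK target genes rose in 6 of 18 cases and 2 fell (adjusted p = 0.330), called without D10P replicate 2 (0.0422). Fibroblast and mesenchyme genes rose in 8 of 19 cases, 9 adjusted over the list alone, and 4 fell (adjusted p = 0.251). Fry called the endothelial, cell cycle exit, epithelial and fibroblast lists.

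The proliferation list was not called in D10P against D4 (adjusted p = 0.329). Of its 29 genes 3 fell, and none did so adjusted over the list alone. Without D10P replicate 1 the list was called downward (adjusted p = 0.0333). The gene that fell most among those above 10 CPM in D4 was VRTN, at least 909-fold lower, and among the others were ADAMTS19, TFAP2C, HOXB1, FOXD3, HOXD1, TTC29, HAGLR and PTPRZ1. Those with the largest rise were CHRNA1, MUSK, MMP13, MAP3K7CL, MYOZ2, MYOG, MLIP, LMOD3, TTN and LINC02397. Tested against a minimum log2 change of 1, 2499 genes passed, 1484 higher and 1015 lower.

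The central comparison sets D10P against D10N, the day-10 cells parted by the MYF5 reporter. Muscle genes were higher in the positive fraction. MYOD1 was at 101 ± 44.4 CPM against 17.6 ± 9.84 in D10N (log2 fold change 2.51 ± 0.45, adjusted p = 0.00281) and MYOG at 159 ± 69.9 against 25.1 ± 21.8 (2.67 ± 0.52, adjusted p = 0.00491). MYH3 differed by 3.43 ± 0.41 (adjusted p = 1.84e-04). Of 19 fibroblast and mesenchyme genes 7 were lower, among them COL3A1 (-2.52 ± 0.52, adjusted p = 0.00726). In all, 1908 genes changed, 1034 higher and 874 lower in D10P.

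Of 15 myogenic regulators 11 rose and none fell, led by MYF5 and SMYD1 (2.89 ± 0.50). Of 43 sarcomere genes 35 rose, 39 adjusted over the list alone, led by MYBPC1 (4.32 ± 0.67) and MYOT (3.79 ± 0.76), and none fell. Excitation-contraction coupling genes rose in 14 of 17 cases, 15 adjusted over the list alone, led by CASQ2 (3.76 ± 0.29). Neuromuscular junction genes rose in 7 of 11 cases, 8 adjusted over the list alone, led by MUSK (2.98 ± 0.40) and CHRNA1 (2.91 ± 0.21). LRP4 fell (-0.53 ± 0.14), a call lost without D10N replicate 1 (adjusted p = 0.0852), D10P replicate 1 (0.0698) or D10P replicate 3 (0.0582). Satellite cell and myoblast surface proteins rose in 5 of 18 cases, 9 adjusted over the list alone, led by CDH15 (2.73 ± 0.52) and ERBB3 (2.59 ± 0.44), and SDC3 fell. Imprinted growth genes rose in 7 of 12 cases, 9 adjusted over the list alone, led by DLK1 (3.39 ± 0.31). Fibroblast and mesenchyme genes fell in 7 of 19 cases and none rose, 1 doing so adjusted over the list alone and 1 being higher at an unadjusted p under 0.05, led by POSTN (-2.64 ± 0.59), whose call was lost with limma-voom (adjusted p = 0.0815). These 7 lists were called with the preset and with an estimated correlation, the latter at adjusted p = 0.0215, 0.0136, 0.00918, 0.0209, 0.0136, 0.0441 and 0.0136 in the order given.

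Muscle energy metabolism rose in 7 of 16 cases, 10 adjusted over the list alone (adjusted p = 0.0824 with an estimated correlation). HOX genes of groups 1 to 5 fell in 4 of 13 cases, 7 adjusted over the list alone, led by HOXA3 (-1.60 ± 0.27; adjusted p = 0.0512 with an estimated correlation). Cell cycle exit genes rose in 3 of 12 cases (adjusted p = 0.0733 with an estimated correlation), and cardiac genes in 3 of 8 (adjusted p = 0.115). Among these cardiac genes were TNNT2, also on the sarcomere list, and MYH6, which may share reads with MYH7. Of the 16 genes of the cardiac list, those not tested did not pass the count filter. Neural genes fell in 6 of 21 cases and DCX (3.41 ± 0.29) and POU4F1 (2.38 ± 0.44) rose (adjusted p = 0.0824 with an estimated correlation). Endothelial and blood genes fell in 2 of 11 cases, 5 adjusted over the list alone, led by CDH5 (-2.77 ± 0.55), and CLDN5 rose (adjusted p = 0.343 with an estimated correlation). BMP target genes fell in 5 of 14 cases and 1 rose, 7 and 2 adjusted over the list alone (adjusted p = 0.484 with an estimated correlation). FGF and ERK target genes fell in 3 of 18 (adjusted p = 0.496), led by EGR2 (-2.29 ± 0.33), and epithelial genes in 2 of 16 (adjusted p = 0.273). The proliferation list was called upward although none of its 29 genes passed edgeR's test, DESeq2 or limma-voom and 2 were higher at an unadjusted p under 0.05 (adjusted p = 0.666 with an estimated correlation). Without D10N replicate 1 edgeR passed 9 of them, all higher, and without D10N replicate 3 it passed 1. Without D10N replicate 3 the calls of BMP (0.283), FGF (0.283), endothelial (0.258), cardiac (0.0640) and cell cycle exit (0.0640) lists were lost. Without D10P replicate 2 those of BMP (0.132), FGF (0.189), endothelial (0.189), epithelial (0.0590) and neural (0.0590) genes were. Without D10P replicate 1 those of BMP (0.229), endothelial (0.0657), epithelial (0.0675) and proliferation (0.382) genes were. Without D10N replicate 2 the epithelial (0.0922), neural (0.167) and proliferation (0.951) calls ended, and without D10N replicate 1 (0.154) or D10P replicate 3 (0.163) the cardiac one. The cardiac call also ended without the count filter (0.188) and without both libraries numbered 3 (0.228), and the BMP call with only the 6 libraries compared (0.0915). Fry did not call the proliferation (0.279), BMP (0.102) or FGF (0.136) list.

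Without D10N replicate 3 the somite list was called by camera (adjusted p = 0.0417), with 2 genes higher and 5 lower. With all libraries 2 of its 18 genes were higher and 3 lower. The sclerotome list (2 of 11 lower) was also called without D10N replicate 3 (0.0322), without both libraries numbered 3 (0.0297) and by fry (0.0109). Without D10P replicate 3 the TGF-beta list was called (0.0126), with 0 genes higher and 5 lower. With all libraries, though, 0 of its 14 genes passed edgeR's test or limma-voom, 1 was lower with DESeq2 and 2 were at an unadjusted p under 0.05. Surface antigens were not called as a list, with 10 of 64 higher and 11 lower, 13 and 15 adjusted over the list alone. Without D10P replicate 3 the list was called downward (adjusted p = 0.0253). MME was at 365 ± 123 CPM in D10P and 241 ± 14.3 in D10N (adjusted p = 0.144). KIT fell (-2.79 ± 0.43). The genes above 10 CPM with the largest rise were MYBPC1, MYF5, MYOT, CASQ2, SMPX, MYH7, TRIM72, CKM, IL17B and MYL11. MYH7 may share reads with MYH6. Those that fell most were UNC5C, ITGA8, EBF2, KIT, CDH5, LRRC15, PAMR1, ADAMTS15, FREM1 and COL3A1. PAX7 (1.40 ± 0.85, adjusted p = 0.369) and PAX3 (-0.30 ± 0.15, adjusted p = 0.278) did not pass the threshold. With the replicate numbers in the table's column names as a block, they did, at 1.43 (adjusted p = 0.0352) and -0.28 (adjusted p = 0.00447), and 5489 genes changed, among them all 1908 with the same sign and 20 of the 29 proliferation genes, all higher. PAX3 also passed without D10N replicate 3 (adjusted p = 0.0171) and without both libraries numbered 3 (0.0163). With the block the BMP (0.0677), neural (0.108) and cardiac (0.136) list calls were lost.

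Fitted with only the 6 libraries compared, 186 genes changed, 130 higher and 56 lower. In that fit MYF5 (adjusted p = 0.0228), CASQ2 (0.0249), CHRNA1 (0.0228) and DLK1 (0.0333) passed, and MYOD1 (0.0974), MYOG (0.168), MYH3 (0.0567), SMYD1 (0.135), MYBPC1 (0.116), CDH15 (0.148) and COL3A1 (0.180) did not. Of 74 named calls that could be refitted, 56 were lost. That fit holds no term for the replicate numbers. With them as a block in the fit of all 15 libraries, chosen after seeing the data, 0 of 78 named calls were lost. The count of changed genes was 3325 without D10N replicate 3 and 4022 without both day-10 libraries numbered 3. Against a minimum log2 change of 1 it was 265, with 197 higher and 68 lower.

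**Figure D3:**
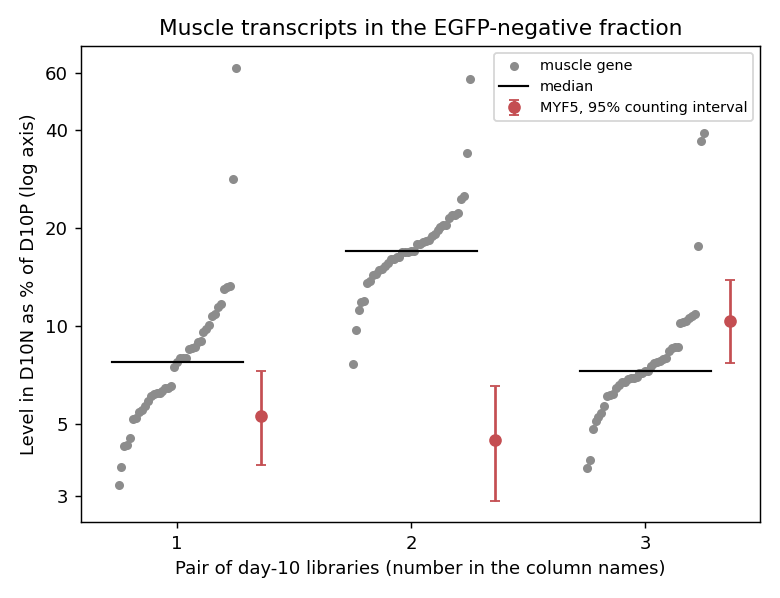
Level in D10N as percent of the level in D10P (vertical log axis) for 41 muscle genes (grey points, ordered by ratio) and MYF5 (red, with its 95% counting interval) in each pair of day-10 libraries. The black line is the median of the 41 genes, at 7.76%, 17.0% and 7.26%, and MYF5 lies at 5.28%, 4.45% and 10.4%.

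Muscle transcripts were also present in the negative fraction. Over 41 muscle genes that were low in D4 and at 10 CPM or more in D10P, the median level in D10N was 7.76%, 17.0% and 7.26% of that in D10P in the 3 pairs of libraries. MYF5 was at 5.28% (95% counting interval 3.74 to 7.26), 4.45% (2.90 to 6.54) and 10.4% (7.66 to 13.8). Intervals and bounds cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

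The comparison of Diff with D10P shows how the further differentiated cells differed from the sorted fraction they came from. Fibroblast and mesenchyme genes rose in 9 of 19 cases and smooth muscle genes in 6 of 10. Sarcomere, excitation-contraction coupling and TGF-beta target genes rose too, but the calls of these 3 lists were lost with an estimated correlation. MYH3 went from 2860.1 ± 750.0 to 7896 ± 933 CPM (log2 fold change 1.47 ± 0.38, adjusted p = 0.0197), a call lost without Diff replicate 2 (adjusted p = 0.0726), D10P replicate 1 (0.0536) or D10P replicate 3 (0.0607). COL3A1, a fibrillar collagen, went from 19.8 ± 12.9 to 1214 ± 362 CPM (5.94 ± 0.60, adjusted p = 3.61e-05). In all, 2802 genes changed, 1707 higher and 1095 lower in Diff.

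Of 19 fibroblast and mesenchyme genes 9 rose, 11 adjusted over the list alone with 2 lower, led by COL3A1 and POSTN (5.75 ± 0.61), and TWIST2 fell (-3.30 ± 0.69). Of 10 smooth muscle genes 6 rose, led by LMOD1 (3.70 ± 0.55) and ACTA2 (3.27 ± 0.20), and none fell. Both lists were called with the preset and with an estimated correlation, the latter at adjusted p = 0.00649 and 0.00448. Another 8 lists were called upward with the preset correlation only. Of 43 sarcomere genes 26 rose, 33 adjusted over the list alone, led by LMOD2 (3.90 ± 0.55) and MYBPC1 (3.28 ± 0.58), and none fell (adjusted p = 0.273 with an estimated correlation). Of 17 excitation-contraction coupling genes 10 rose, led by SLN, a regulator of the calcium pump, at a ratio of 32.4 to 984 (adjusted p = 0.159 with an estimated correlation). Muscle energy metabolism rose in 5 of 16 cases, led by CKMT2 (2.77 ± 0.54) and CKM (2.74 ± 0.50; adjusted p = 0.493 with an estimated correlation). TGF-beta and activin target genes rose in 9 of 14 cases, 12 adjusted over the list alone with 1 lower, led by LEFTY1 (a ratio of 15.2 to 3466) and NODAL (3.89 ± 0.55), both low in CPM (adjusted p = 0.165 with an estimated correlation). LEFTY1 may share reads with LEFTY2. BMP target genes rose in 8 of 14 cases, with 2 lower adjusted over the list alone, led by SMAD7 (3.80 ± 0.61) and ID4 (3.70 ± 0.52; adjusted p = 0.176 with an estimated correlation). Cardiac genes rose in 3 of 8 cases, led by NPPB (a ratio of 47.0 to 10478), and 1 fell (adjusted p = 0.159 with an estimated correlation), and that call was lost without the count filter (adjusted p = 0.500).

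Wnt target genes rose in 5 of 16 cases, 8 adjusted over the list alone, and LEF1 fell (-1.52 ± 0.39), a call lost without Diff replicate 2 (adjusted p = 0.0780) or D10P replicate 3 (0.0624), with limma-voom (0.102) and with only the 6 libraries compared (0.0517). That list had adjusted p = 0.273 with an estimated correlation, 0.0642 without D10P replicate 2 and 0.0891 without Diff replicate 3. Neuromuscular junction genes rose in 3 of 11 cases, led by LRP4 (2.19 ± 0.14), with adjusted p = 0.610 with an estimated correlation and 0.0676 without Diff replicate 1. Without the count filter the Wnt list (0.0824) and the junction list (0.187) were not called, nor with only the 6 libraries compared, both at 0.100. Without both day-10 libraries numbered 3 the Wnt, junction and cardiac lists each had adjusted p = 0.0713.

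The myogenic regulators did not move as a list in Diff. Of 15 tested 2 rose, led by MYF6 (1.46 ± 0.16), and MYF5 (-0.85 ± 0.25, adjusted p = 0.0338) and MEF2A (-0.53 ± 0.12) fell, MEF2A not with only the 6 libraries compared (adjusted p = 0.0735). The MYF5 call was lost without Diff replicate 1 (adjusted p = 0.0972), 2 (0.116) or 3 (0.0600) and without D10P replicate 1 (0.128) or 2 (0.0583). MYOD1 (65.8 ± 29.7 CPM in Diff, adjusted p = 0.383) and MYOG (325 ± 81.8 CPM, adjusted p = 0.186) did not differ from D10P past the threshold, though MYOD1 was lower without both day-10 libraries numbered 3 (log2 fold change -0.95, adjusted p = 0.0263), nor did PAX7 (adjusted p = 0.488), PAX3 (0.863) or MME (0.277). None of 29 proliferation genes passed edgeR's test, DESeq2 or limma-voom in Diff against D10P, and 1 was lower at an unadjusted p under 0.05. The list was not called (adjusted p = 0.214), but without D10P replicate 2 it was, downward (adjusted p = 0.0250). Of 18 satellite cell and myoblast surface proteins 3 rose and 2 fell, and camera did not call the list (adjusted p = 0.467). CALCR (4.53 ± 0.33) and VCAM1 (3.78 ± 0.50) rose most, and CXCR4 fell most (-1.43 ± 0.30).

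Among the other lists not called in Diff against D10P, epithelial genes rose in 4 of 16 cases, 5 adjusted over the list alone with 1 lower. That list was called with only the 6 libraries compared (adjusted p = 0.0460) and without Diff replicate 1 (0.0359) or D10P replicate 3 (0.0498). FGF and ERK target genes fell in 4 of 18 cases, 6 adjusted over the list alone, and 1 rose, and endothelial and blood genes fell in 3 of 11 cases and 1 rose, 4 and 2 adjusted over the list alone. Both were called without D10P replicate 1 (0.0411 and 0.0468) or 2 (0.00133 and 0.0335). Surface antigens rose in 13 of 64 cases and 8 fell, 16 and 14 adjusted over the list alone, called without D10P replicate 3 (0.0432). Fry called the satellite cell surface (0.0405), cell cycle exit and sclerotome lists, the last 2 at 0.0304.

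The genes above 10 CPM with the largest rise in Diff were CALB1, AFP, COL3A1, EDN1, POSTN, LRP2, EBF3, GBP1, ACTG2 and DCN. AFP, a fetal liver protein, was at 36.5 ± 29.7 CPM in Diff, with the libraries between 10.1 and 68.7 CPM. Among those that fell most were VGF, JCHAIN, UNC5A, TRBC2, RAB3C, C1QTNF1, FAM20A, GALNT6 and NFASC. TRBC2 may share reads with TRBC1, and the call of VGF (-4.95 ± 0.90) was lost with limma-voom (adjusted p = 0.0737). With only the 6 libraries compared 1650 genes changed and 20 of 89 named calls were lost, without Diff replicate 2 there were 1793, and against a minimum log2 change of 1 there were 399, with 329 higher and 70 lower. Without both day-10 libraries numbered 3 the count was 5456.

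**Figure D4:**
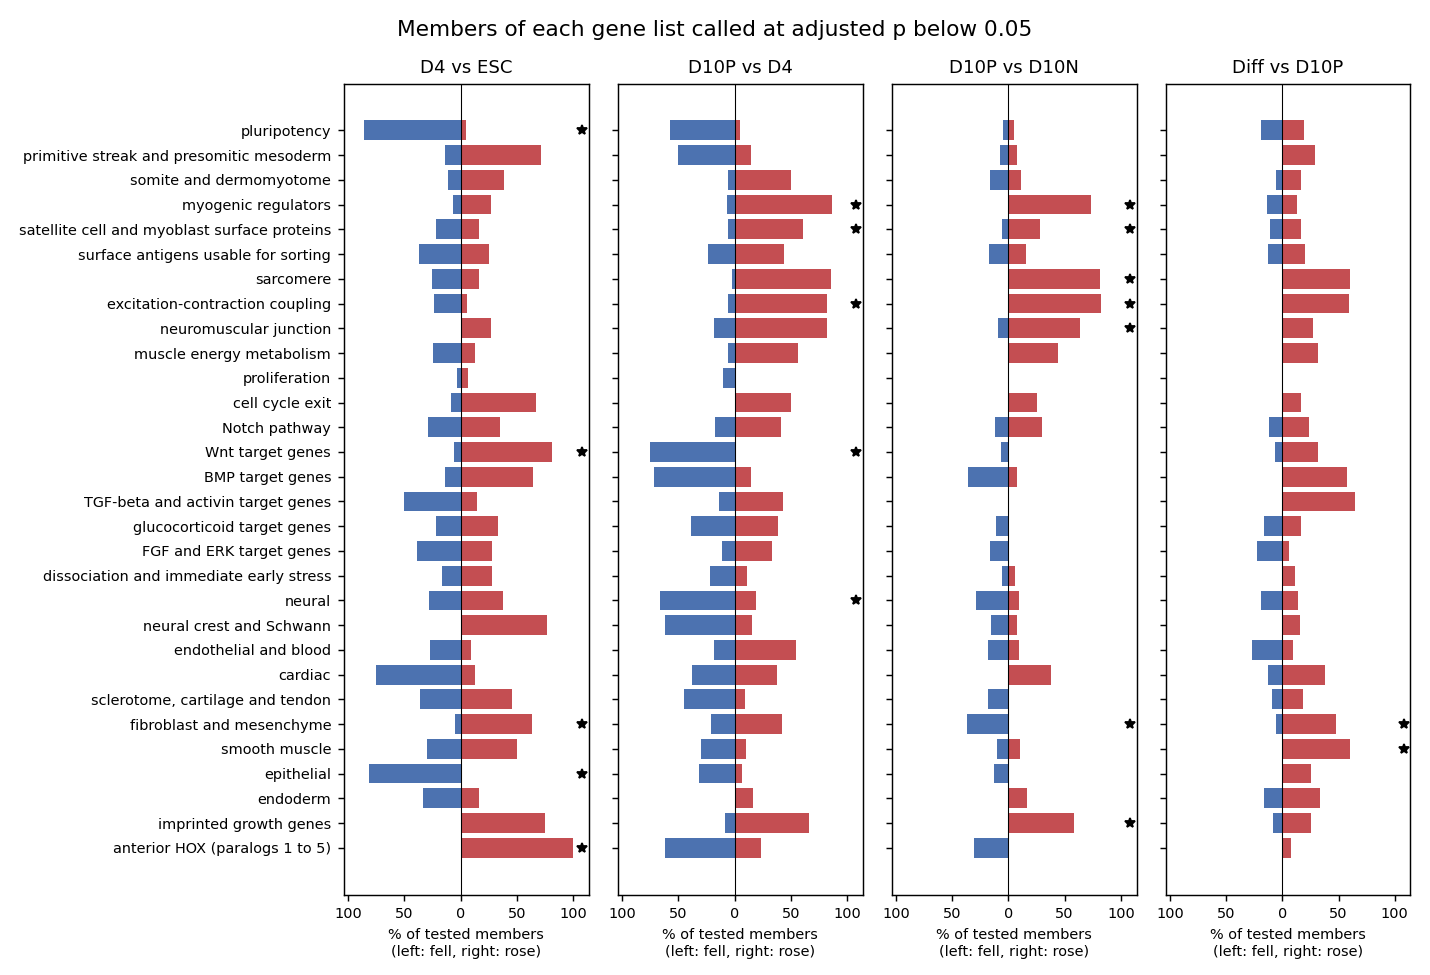
Percent of the tested members of each gene list that rose (red, right) or fell (blue, left) in each of the 4 comparisons at adjusted p below 0.05, with a star where camera with an estimated correlation also called the list. The sarcomere list rose in 37, 35 and 26 of 43 genes in the comparisons D10P with D4, D10P with D10N and Diff with D10P.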

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

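The replicate block and the fit without both day-10 libraries numbered 3 were chosen after seeing the data, and the others were planned. RLE factors, both other low-count filters, DESeq2 and limma-voom kept each count of changed genes within 1.5 times. RLE factors changed no list call. Genes called both in an alternative and in the fit of all 15 libraries kept their sign in each alternative.

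Counts moved by more under other settings. Against a minimum log2 change of 1, 3253 genes passed for D4 against ESC, 2499 for D10P against D4, 265 for D10P against D10N and 399 for Diff against D10P, since that test asks for more than a difference. At an adjusted p of 0.01 there were 940 for D10P against D10N and 1428 for Diff against D10P. With only the 6 libraries compared there were 186 for D10P against D10N, of which 185 were among the 1908, and 1650 for Diff against D10P. For D4 against ESC that count rose instead, from 9440 to 12396, and for D10P against D4 it was 6796. The fit of all 15 libraries shares 1 estimate of the spread over the groups. Replicates differed by a chi-square per degree of freedom of 2.27 to 3.52 in ESC and 30.1 to 90.2 in D10N. The cause was not tested. With the replicate block 5489 genes changed between D10P and D10N, and the block changed the calls of PAX7, PAX3 and the BMP, neural and cardiac lists and no other call of a named gene or list. Without both day-10 libraries numbered 3 there were 4022 and, for Diff against D10P, 5456. The first component held 64.2% of the variance with 2000 genes and 72.4% with a prior count of 0.5.

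Leaving out 1 library gave 8282 to 8450 genes for D4 against ESC, 6621 to 7937 for D10P against D4, 1306 to 3325 for D10P against D10N (the highest without D10N replicate 3), 1793 to 3194 for Diff against D10P (the lowest without Diff replicate 2), and 13255 to 15436 over the 5 groups.

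Of 1245, 1470, 1087 and 1190 values of called named genes in the alternatives of the 4 comparisons, in the order above, 1214, 1399, 968 and 1069 kept direction and side of the threshold. Of the list tests in the alternatives 1308 kept both, 82 lost a call and 45 gained one. Gene calls gained outside the block were those of MYF5 (D4 against ESC), PAX3 (D10P against D10N), MYOD1 and, at -1.90 (adjusted p = 0.00853) without both libraries numbered 3, TBX6 (both Diff against D10P). The 15 fold changes that turned sign belong to genes not called in any of them. MYH3 in D4 against ESC (0.00) was -0.0349 with RLE factors, -0.0196 with at least 1 CPM in 3 libraries, -0.0350 with DESeq2, and -0.0554 to 0.00973 with 1 library left out, below 0 without ESC replicate 1 or 3 or D4 replicate 1 or 2. PAX3 in D10P against D4 (-0.03) was 0.0769 without both libraries numbered 3 and -0.122 to 0.0787 with 1 left out, above 0 without D4 replicate 1 or D10P replicate 3. In Diff against D10P (-0.06) it was -0.179 to 0.0306, above 0 without D10P replicate 2. TBX6 in D10P against D4 (0.42) was -0.309 to 0.797, below 0 without D10P replicate 2. In D10P against D10N (0.05) it was -0.0236 without both libraries numbered 3 and -0.684 to 0.621 with 1 left out, below 0 without D10N replicate 3 or D10P replicate 2. The cause was not tested.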

Other observations

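Another 4 lists and the posterior HOX genes moved in part. Of 17 Notch pathway genes 6 rose and 5 fell in D4 against ESC, 7 rose and 3 fell in D10P against D4, 5 rose and 2 fell in D10P against D10N, and 4 rose and 2 fell in Diff against D10P. HEY1, a Notch target, rose in D10P over D4 (7.60 ± 0.41). Of 18 glucocorticoid target genes 6 rose and 4 fell by day 4, with ZBTB16 rising most (6.77 ± 0.72). In D10P against D4 7 rose and 7 fell, ZBTB16 among those that fell (-4.11 ± 0.57). The first medium holds dexamethasone, a glucocorticoid, whose effect was not tested. Of 18 dissociation and immediate early genes 1 rose and 1 fell between the sorted fractions, HSPB1 (1.17 ± 0.20) and JUN (-1.46 ± 0.30). Of 6 endoderm genes 2 rose in Diff, led by AFP, and 1 fell. None of these 4 lists was called by camera in the 4 comparisons, though the dissociation list was in Diff against D10P without both day-10 libraries numbered 3 (adjusted p = 0.0487). The 4 tested posterior HOX genes, HOXB6 to HOXB9, were too few for a set test. HOXB9 rose at least 348-fold by day 4, and HOXB6 (4.03 ± 0.38) rose most in D10P over D4.

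The splits of the samples were planned, and the other tests in this part were chosen after the result was seen. In D4 against ESC, D10P against D4 and Diff against D10P, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes as the 9440, 7806 and 2802 found, and the highest other gave 0. With 10 splits no share under 0.05 can be had. In D10P against D10N 3 of 10 splits gave 1908 genes or more, and the highest other gave 3787. The splits that gave more set the libraries numbered 2 and 3 apart, a structure of the samples besides the fraction. Among the 4 splits that part all 3 pairs the others gave 0, and the block gave 5489. For the 5 groups 1 of 100 splits, the real one, gave 13970, and the highest other was 5420. That argues against a random grouping of all 15 libraries. The other splits mix libraries of the 5 groups, so the result says nothing on any single comparison.

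PAX7 was higher at day 4 than at day 10. Reads shared with PAX3 would keep PAX7 at a like percent of PAX3, but it was 21.8% (18.4 to 27.3) in D4 and 0.737% (0.115 to 1.31) in D10P, a fold of 29.6, which argues against them. Neural crest cells at day 4 may be a source, since 7 of 13 tested neural crest genes rose by day 4 and fell by D10P, just past a limit of more than 50% set after the values were seen. Paraxial mesoderm cells stay open, with 7 of 18 somite genes higher at day 4, PAX7 itself among them, and TBX6 lower. Of these 7 only PAX7 fell again in D10P, and the others need not have fallen if myogenic cells keep them. Both cell types are hypotheses, and FOXD3, ERBB3, SOX9 and NGFR stand on other lists too.

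Muscle transcripts in the negative fraction may come from 1 share of average EGFP-positive cells or from myocytes past MYF5 expression. Off the pair median, 10 of 41 muscle genes lay past the threshold in a moderated t-test over the 3 pairs, 5 above, among them MYF6 and MYOD1, and 5 below, among them MYBPC1 and MYOT. In an ordinary t-test none did (8 at an unadjusted p under 0.05), so a single share as the only source of all 41 is argued against only if the spread is shared over genes, and it stays open. A first count, of 6 genes off beyond counting error in all 3 pairs, is not used, since libraries differ by more than counting error. A test on sarcomere genes alone was written after that count was seen. In it 20 of 25 sarcomere genes lay within 1.5-fold of the median in all 3 pairs, exactly at its limit of 80%, and MYF5 did in 2, so for sarcomere genes a single share stays open. MYF5 lay below the muscle median beyond its interval in 2 of 3 pairs and above it in the other. The fractions were sorted by the MYF5 reporter, so the sort itself can lower the MYF5 ratio whatever the source. This ratio therefore cannot decide, and the myocytes stay open too.

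Of 19 fibroblast and mesenchyme genes 9 were higher in Diff than in D10P, and so were 9 of 14 TGF-beta target genes, whose list's call was lost with an estimated correlation (adjusted p = 0.165). The end of TGF-beta receptor inhibition is a candidate explanation, since the last medium lacks SB431542. Of 12 tested target genes on neither the fibroblast nor the smooth muscle list 7 rose (SKIL, PMEPA1, CCN2, SMAD7, LEFTY1, LEFTY2 and NODAL). None fell by edgeR (1 of all 14 was lower at an unadjusted p under 0.05, and none with DESeq2 or limma-voom). Of the 7, 6 had fallen by day 4, and the result was just past a limit set after the values were seen. LEFTY1, LEFTY2 and NODAL are also on the pluripotency list, so a fall by day 4 cannot be told from the loss of pluripotency. With these left out, the genes that rose would not be a majority of those tested, so the test cannot decide. More fibroblasts could account for the 9 of 19 fibroblast genes that rose, with COL3A1 at 1214 ± 362 CPM and COL1A1 at 1498 ± 267, and TWIST2, near the floor, fell. That stays open, and the sort before the last step, the time and the medium cannot be told apart by these groups.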
